A study of Arabidopsis thaliana with 4 samples.

How the data were processed

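RNA was measured on 4 Agilent Arabidopsis 2 oligonucleotide arrays with 2 dyes each, per the labels. On every array the green dye (Cy3) marked wild type and the red dye (Cy5) marked fas1-2, fas2-2, or wild type 6 h or 12 h after irradiation, so the dye orientation was the same throughout and no dye swap was used. Tissue is given differently in 2 places: the sample labels name rosette leaves and the design text names seedlings without roots. The labels do not say whether arrays shared a wild-type RNA, how many plants were pooled, or at what time of day plants were taken.

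The deposited values are 1 log10 ratio per feature and array, as read here; the submitters' processing notes name Agilent Feature Extraction, with no version, background correction or dye normalization stated. Log10 of red over green was assumed because it is the scale of that software; the deposited values ran from -1.80 to 1.66. The base and the sign cannot be settled from the labels. Each column's median was near 0 (-0.0008 for fas1-2, -0.0014 for fas2-2, -0.0014 at 6 h and -0.0004 at 12 h), so the arrays came centred. Spot intensities were not used here, so neither signal over background nor saturation could be judged, and no spot was filtered. Exact zeros numbered 131 to 245 per array and were kept.

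The values were multiplied by 3.32 to give log2 ratios. Of 22575 features, 9335 had a single gene name in the array annotation of 2007, 40 had several and 13200 had none. Features with several names or none were left out of the gene tests, and a feature without a name is unnamed here, not without a gene. Through their gene identifiers, 9317 of the 9335 were matched to the current reference list (assembly TAIR10.1), used for symbols and the order of loci, and 18 kept the array's name. Probes of a gene were averaged (79 of 9253 genes had several). No build is named for the array, so no coordinates are given. For 48 transcripts spotted more than once (99 spots), the pooled SD between spots was 0.24 to 0.28 on the log2 scale, and the median SD 0.10 to 0.13.

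The main test was limma (version 3.58.1, R 4.3.3): lmFit and eBayes on all 4 arrays with a mean for the mutants and a mean for the irradiated arrays, each tested against 0, and their difference. This leaves 2 residual degrees of freedom, to which eBayes added 1.78. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The spread is that between the 2 mutants and between the 2 times, so a gene that differs between them is not called; the control's own spread, and any dye effect of a gene in the tests against 0, are left out. The labels do not say that the RNAs came from separate cultures. Single arrays were described by values and by counts of probes at least 2-fold from control.

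Gene lists were tested with camera (preset correlation 0.01, lists of at least 3 measured genes, Benjamini-Hochberg over 36 lists), with an estimated correlation as an alternative. Per array, a list's median was placed among 10000 random lists of the same size, not matched on expression since no intensities were used. The design, the alternatives, the rule for named genes and 23 lists were fixed before the data were examined. Only 39 of the 301 genes in these 23 lists had a named probe, 5 lists had none, and 5 could be tested. Therefore 31 lists of gene families were added from gene symbols after the annotation was seen. Of these, 5 were narrowed after the top genes had been seen, and 3 genes were taken out after list values had been seen, because their symbols only resemble the family's: AT-HF from the histones, JRG21 from the jacalin lectins and the cyclophilin CYP71 from the P450 genes.

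Named genes followed a rule: the 10 highest and 10 lowest genes by the smaller of the 2 values of a setting, the 5 highest and 5 lowest per array, list members that passed or else the 4 with the largest mean change and any at least 2-fold, the 5 largest differences each way between mutants and between times, and the 10 largest each way between settings. Members of the added lists were named by the same rule for lists, and all genes that passed are named. FAS1 and FAS2 were to be given on every array and are not reported here. The genes named are those of the rule that bear on each comparison, not all of them.

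The limma and camera steps were tested on simulated data with 200 of 9253 genes changed and variances drawn from the fitted prior. For the mutants, of 50 genes at each size, 32 were recovered at a log2 change of 1, 43 at 2, 46 at 3 and 49 at 4, with 11 unchanged genes called. For irradiation these were 32, 46, 47 and 50, with 4 unchanged genes called. The simulated change was the same on both arrays of a setting, and no shared control was included. Recovery of genes whose change differs between mutants or between times was therefore not measured. Arrays that share a control were simulated 50 times on unchanged genes with the measured spread, giving the control the same variance as the other RNA; this assumption fixes the correlation between such arrays. Alternatives were centring, scaling between arrays, all features, single probes, robust moderation, only the arrays of the comparison, other thresholds, leaving out each array, rank-based camera, Spearman correlation and other log bases; fits without genes holding an exact zero, tests of the earlier lists alone and lists with the 3 genes put back were chosen after seeing the data. Splits of the samples into other groups were not made, since each condition had 1 array. Placement of genes along chromosomes was compared with 10000 random placements, at neighbour distances of 1, 5, 10 and 20 measured genes and a run of 500. Figures and the placement tests used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.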

Results

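Transcript levels were compared by 2-colour microarray in 2 settings in Arabidopsis thaliana of the ecotype Nossen. In the first setting, plants carrying fas1-2 or fas2-2, mutations in the p150 and p60 subunits of chromatin assembly factor 1 (CAF-1), were each compared with wild type. CAF-1 is the chaperone that places histones H3 and H4 on newly replicated DNA. In the second setting, wild-type plants taken 6 h or 12 h after 100 Gy of gamma-rays, given at 300 Gy/h, were compared with non-irradiated wild type. All plants were 4 weeks old. Each of the 4 conditions had 1 array, so no condition had replicates, and the tests below use the spread between the 2 mutants and between the 2 times. The mutant or irradiated RNA carried the red dye on every array. Ratios are given on the log2 scale as red over green; the log base and the direction are not stated in the labels and were taken as those of the scanner software, so fold sizes and signs rest on that reading. After matching, 9253 genes had a probe with a single gene name. FAS1 and FAS2 themselves were not analysed here, so the genotype labels were not checked on the mutated genes.

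The number of probes at least 2-fold from wild type was 268 of 9335 in fas1-2 (148 higher, 120 lower) and 293 in fas2-2 (166 higher, 127 lower). After irradiation it was 269 at 6 h (176 higher, 93 lower) and 155 at 12 h (85 higher, 70 lower); with the arrays scaled to 1 spread these were 262 and 250, so the lower count at 12 h depends on the scaling. The number of arrays limits the precision of every value.

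The first comparison asked which transcripts were altered when CAF-1 was lost, whichever subunit was mutated. In limma, 11 genes changed, 7 upward and 4 downward. The genes that rose were AT1G27030 by a log2 ratio of 2.14 (SE 0.068), AT5G53150 by 2.15 (SE 0.099), AT4G31570 by 2.05 (SE 0.10), AT1G65220 by 2.04 (SE 0.086), AT5G18850 by 1.65 (SE 0.069), AT1G68570 by 1.53 (SE 0.075) and AT4G11410 by 1.46 (SE 0.067). AT1G68570 encodes NPF3.1, a transporter of the nitrate and peptide transporter family. The genes that fell were AT2G20670 (-2.35, SE 0.12), AT5G19120 (-1.68, SE 0.064), AT3G02900 (-1.53, SE 0.076) and AT5G26360 (-1.37, SE 0.065). All 11 had the same adjusted p of 0.0487 in limma and moved the same way on both mutant arrays. At an unadjusted p under 0.05 there were 1934 genes, where 463 would be expected by chance if the spread between arrays held all error. That spread leaves out the control's own spread and dye effects. A shared control or a dye effect could therefore raise the number without any change in the genes. The 11 calls were lost when each array was centred on its median, where the smallest adjusted p was 0.0514, and with scaling, robust variance moderation or any array left out.

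The 2 measured genes of the flavonoid and anthocyanin list were about 4-fold above wild type in each mutant. DFR (AT5G42800), which makes leucoanthocyanidins, stood at 2.13 in fas1-2 and 2.04 in fas2-2, and UF3GT (AT5G54060), which glycosylates anthocyanins, at 1.95 and 1.88. Their adjusted p was 0.0796 over all genes and 0.000787 adjusted over the list alone. UGT78D2 (AT5G17050), a flavonoid glucosyltransferase outside that list, stood at 0.11 and 0.73. Other genes high in both mutants were AT5G53820 (2.76 and 2.05), AT5G15500 (2.42 and 1.96), AT5G24210 (2.01 and 2.84) and AT5G51440 (1.93 and 2.23).

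**Figure D1:**
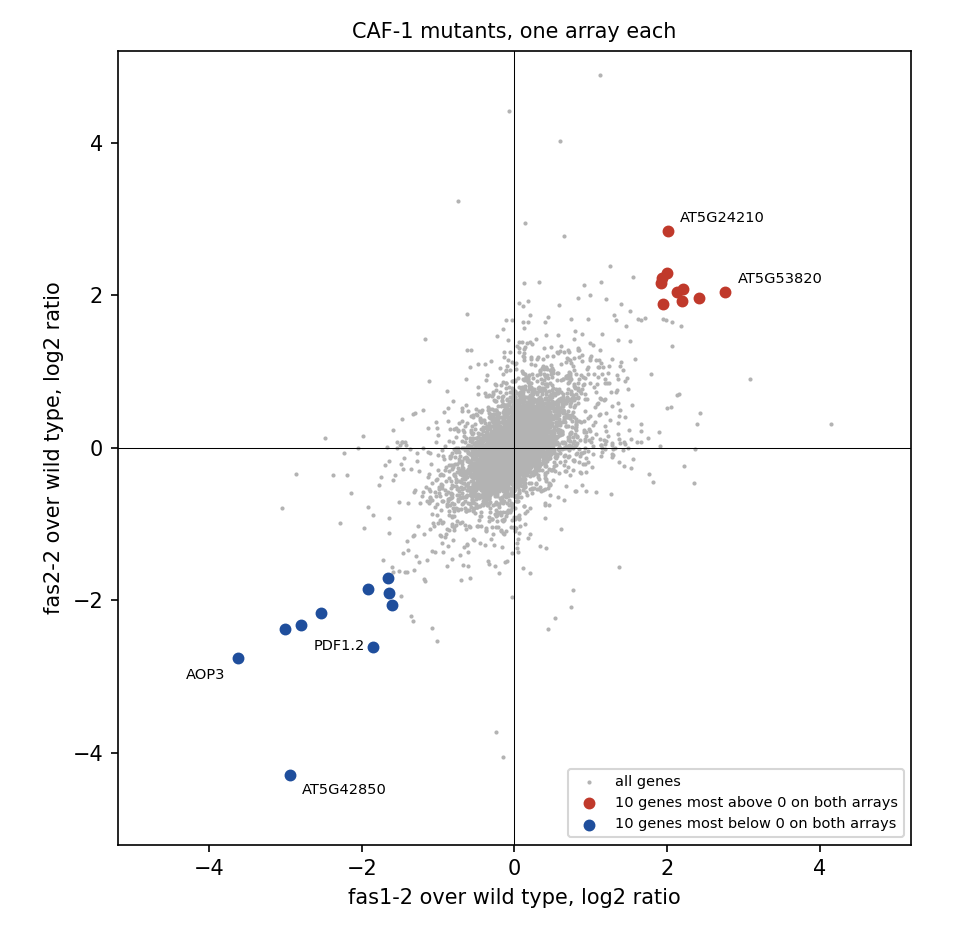
Log2 ratio over wild type in fas1-2 (horizontal axis) and fas2-2 (vertical axis), 1 point per gene for 9253 genes, from 1 array each. The 10 genes most above 0 on both arrays are red and the 10 most below 0 are blue; AT5G42850 lies at -2.95 and -4.29, and the correlation across genes is 0.523.

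Among the genes lowest in both mutants, AT5G42850 stood at -2.95 in fas1-2 and -4.29 in fas2-2, AOP3 (AT4G03050), a dioxygenase of glucosinolate side-chain modification, at -3.62 and -2.76, and AT3G15450 at -3.01 and -2.38. PDF1.2 (AT5G44420), a defensin used as a marker of jasmonate and ethylene signalling, stood at -2.79 and -2.33, with an adjusted p of 0.122 over all genes and 0.00858 adjusted over the list alone. The zinc finger gene STZ (AT1G27730) was at -1.64 and -1.12, with an adjusted p of 0.163 over all genes. AT1G23390 (-1.85 and -2.60), AT4G19630 (-1.92 and -1.85), AT3G15630 (-1.64 and -1.90) and AT1G35320 (-1.60 and -2.07) completed the genes lowest in both. DFR, UF3GT, PDF1.2, AT5G42850, AT5G53820, AT5G51440 and AT5G53150 lie in a stretch of chromosome 5 that holds more 2-fold genes than random placement gives, so a difference between the lines linked to that stretch is not ruled out for them.

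More histone genes lay above 0 than below it in the mutants, 11 of 14 in fas1-2 and 10 of 14 in fas2-2. The list was not called (direction up, unadjusted p = 0.0361 and adjusted p = 0.293 in camera). The 14 measured histone genes had medians of 0.02 in fas1-2 and 0.31 in fas2-2, the latter at the 99.9th percentile of random lists of the same size. The H4 gene AT3G53730 stood at 0.43 and 1.03, but the H4 gene AT5G59690 at 0.60 and -1.06 and the H3.1 gene AT5G10400 at 0.02 and -0.42. Among replication and division genes, the replication helicase subunit MCM7 (AT4G02060, symbol PRL) at 0.43 and 0.58, and the Aurora kinase AUR3 (AT2G45490) at 0.27 and 1.09. ASF1A (AT1G66740), the measured member of the histone chaperones, was at -0.12 and -0.04. The 16 beta-glucosidase genes had medians of 0.12 and 0.48, with BGLU46 (AT1G61820) at 1.2 and 1.95 and BGLU33 (AT2G32860) at 1.24 and 1.07. The 5 jacalin lectin genes had medians of 0.37 in each mutant, with JAL23 (AT2G39330) at 1.04 and 0.80. No list of the 36 tested with camera passed in the mutants. The smallest adjusted p was 0.244, shared by the beta-glucosidases and the jacalin lectins, and 5 lists had an unadjusted p under 0.05. None passed with an estimated correlation. The root genes PYK10 (AT3G09260; 0.34 and 1.0) and EXPA7 (AT1G12560; -0.03 and 0.73) stood higher in fas2-2 than in fas1-2.

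Of the 39 measured genes in lists fixed before the data were examined, 0 passed in limma over all genes in either comparison. Adjusted over the list alone, 9 passed in the mutants (5 higher, 4 lower) and 5 after irradiation (2 higher, 3 lower). These shares are similar to those of all genes at an unadjusted p under 0.05, 1934 and 1354 of 9253. LIG4 and DME in the mutants and LIG4, SIM, GI and TRY after irradiation were the only measured genes of their lists, so their p was not adjusted at all.

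The 2 mutants were then set against each other, without a test. Across genes their ratios correlated at a Pearson r of 0.523 (Spearman 0.529). They shared 45 genes at least 2-fold higher and 40 at least 2-fold lower, where independent lists would share 2.59 and 1.6. Simulated unchanged genes gave 14.6 at 2-fold the same way in both mutants without a shared control. With a shared control they gave 93.1, a count that rests on the assumption that control and mutant RNA vary equally. Only 2 genes were at least 2-fold in opposite directions, where independent lists would give 4.07. Genes much further from wild type in fas2-2 than in fas1-2 included AT5G49500 (1.12 in fas1-2, 4.88 in fas2-2), AT2G19610 (-0.08, 4.42), AT2G15220 (0.60, 4.02), AT1G44920 (-0.73, 3.24), AT1G52100 (0.14, 2.94), AT2G38950 (-0.15, -4.05) and AT5G24760 (-0.25, -3.72); AT5G49500 lies in the stretch of chromosome 5 named above. The reverse held for AT3G44670 (4.15 in fas1-2, 0.31 in fas2-2), AT5G20790 (3.09, 0.91), AT5G37940 (2.43, 0.46), AT4G18250 (-3.05, -0.79) and AT5G40500 (-2.86, -0.35). The labels do not say whether both mutant arrays used the same wild-type RNA. A shared control would by itself make unchanged genes agree between the 2 arrays, by an amount that was not estimated from these data.

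The second comparison asked which transcripts were altered after irradiation. The highest ratio at both times was that of AT3G45730, at 4.62 at 6 h and 4.05 at 12 h. It was followed by AT1G51130 (2.37 and 2.14), AT5G62080 (1.77 and 2.2), AT1G10050 (2.05 and 1.6), AT2G37240 (2.22 and 1.6), AT1G23000 (1.71 and 1.7), AT1G20970 (1.53 and 1.69), AT4G27290 (1.91 and 1.51) and AT2G21640 (2.27 and 1.5). AMS (AT2G16910), a transcription factor of the anther tapetum, stood at 1.73 and 3.42. The lowest at both times were AT4G11290 (-1.63 and -1.79), AT5G62280 (-1.26 and -1.48), AT5G50830 (-1.11 and -2.79), AT1G74140 (-1.06 and -1.40), AT5G62750 (-1.22 and -1.02), AT5G55180 (-2.07 and -1.01), AT5G04960 (-2.41 and -0.99) and the expansin EXPA8 (AT2G40610; -1.55 and -0.99). No gene passed in limma, with or without any one array. The smallest adjusted p was 0.165, for AT3G45730 and AT4G11290. At an unadjusted p under 0.05 were 1354 genes, where 463 would be expected if the spread between arrays held all error.

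**Figure D2:**
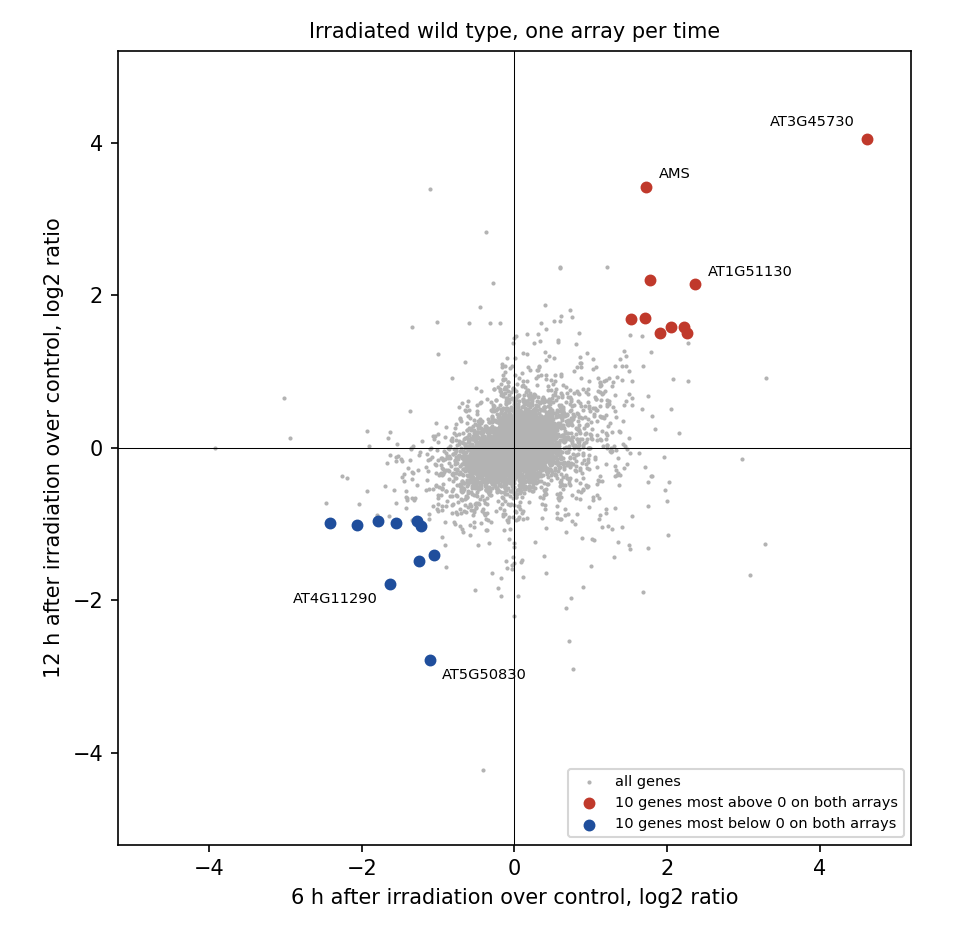
Log2 ratio over non-irradiated wild type 6 h (horizontal axis) and 12 h (vertical axis) after irradiation, 1 point per gene for 9253 genes, from 1 array per time. The 10 genes most above 0 at both times are red and the 10 most below 0 are blue; AT3G45730 stands apart at 4.62 and 4.05.

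The histone genes fell as a list (adjusted p = 0.0123 in camera), with 11 of 14 below 0 at each time. The call was lost with an estimated correlation (p = 0.218) and without the 6 h array (adjusted p = 0.131). Their median was -0.55 at 6 h and -0.26 at 12 h. The H4 genes AT5G59690 (-1.55 at 6 h, -0.72 at 12 h) and AT1G07820 (-1.02, -0.49), the H2B gene HTB2 (AT5G22880; -1.32, -0.68) and the H3.1 genes AT5G10400 (-0.95, -0.36) and AT5G65360 (-0.68, -0.36) were among the lowest. The H3.3 genes AT4G40040 (0.24, 0.12) and AT5G10980 (0.24, 0.13), whose protein is also deposited outside replication, lay above 0. No single histone gene passed. The list of photosystem and thylakoid genes fell as well (adjusted p = 0.0344), a call also lost with an estimated correlation (p = 0.210) and without the 6 h array (adjusted p = 0.131). The median of its 18 members was -0.13 at 6 h and -0.18 at 12 h, and PSBW (AT2G30570) was lowest at -1.06 and -0.76. PSBW was also at -0.81 and -0.90 in the mutants, where the list as a whole had medians of 0.18 in fas1-2, with 13 of 18 above 0, and 0.00 in fas2-2.

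The autophagy genes rose as a list (adjusted p = 0.00336), and all 10 were above 0 at both times. This call too was lost with an estimated correlation (p = 0.269) and without the 6 h array (adjusted p = 0.131). Their median was 0.37 at 6 h and 0.12 at 12 h. ATG8E (AT2G45170) stood at 1.21 and 0.43, ATG8H (AT3G06420) at 0.85 and 0.04, and APG8A (AT4G21980) at 0.82 and 0.25. With an estimated correlation the adjusted p of each of the 3 lists was 0.963. These lists are gene families drawn up after the annotation had been seen, and the 5 lists fixed earlier that could be tested gave no call. The core H3 and H4 genes fixed earlier had medians of -0.68 and -0.36, with an adjusted p of 0.294 in camera over all lists. The gene AT-HF was taken out of the histones after list values were seen; with it put back the histone list has an adjusted p of 0.0344.

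The 10 genes of chromosome segregation and cytokinesis had medians of -0.51 and -0.10 (adjusted p = 0.0785 in camera), a list that was not called. Its adjusted p was 0.00226 without the 12 h array, 0.360 without the 6 h array and 0.963 with an estimated correlation (p = 0.311). KINESIN-12B (AT3G23670), a motor of the phragmoplast, stood at -1.44 and -0.44, the Aurora kinase AUR2 (AT2G25880) at -1.42 and -0.57, and the condensin subunit ATSMC2 (AT3G47460) at -1.06 and 0.12. The topoisomerase gene TOPII (AT3G23890), listed under repair, was at -1.91 and 0.03, the centromeric histone gene HTR12 (AT1G01370) at -0.92 and -0.05, MCM7 at -0.49 and -0.02, and the DNA polymerase alpha subunit ICU2 (AT5G67100) at -0.51 and 0.17. SIM (AT5G04470), an inhibitor of cyclin-dependent kinases that promotes endoreduplication, stood at 1.17 and 0.87 (adjusted p = 0.197 over all genes). LIG4 (AT5G57160), the ligase of DNA end joining, stood at 0.48 and 0.28. The 11 measured repair and damage tolerance genes had medians of -0.02 and 0.31.

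**Figure D3:**
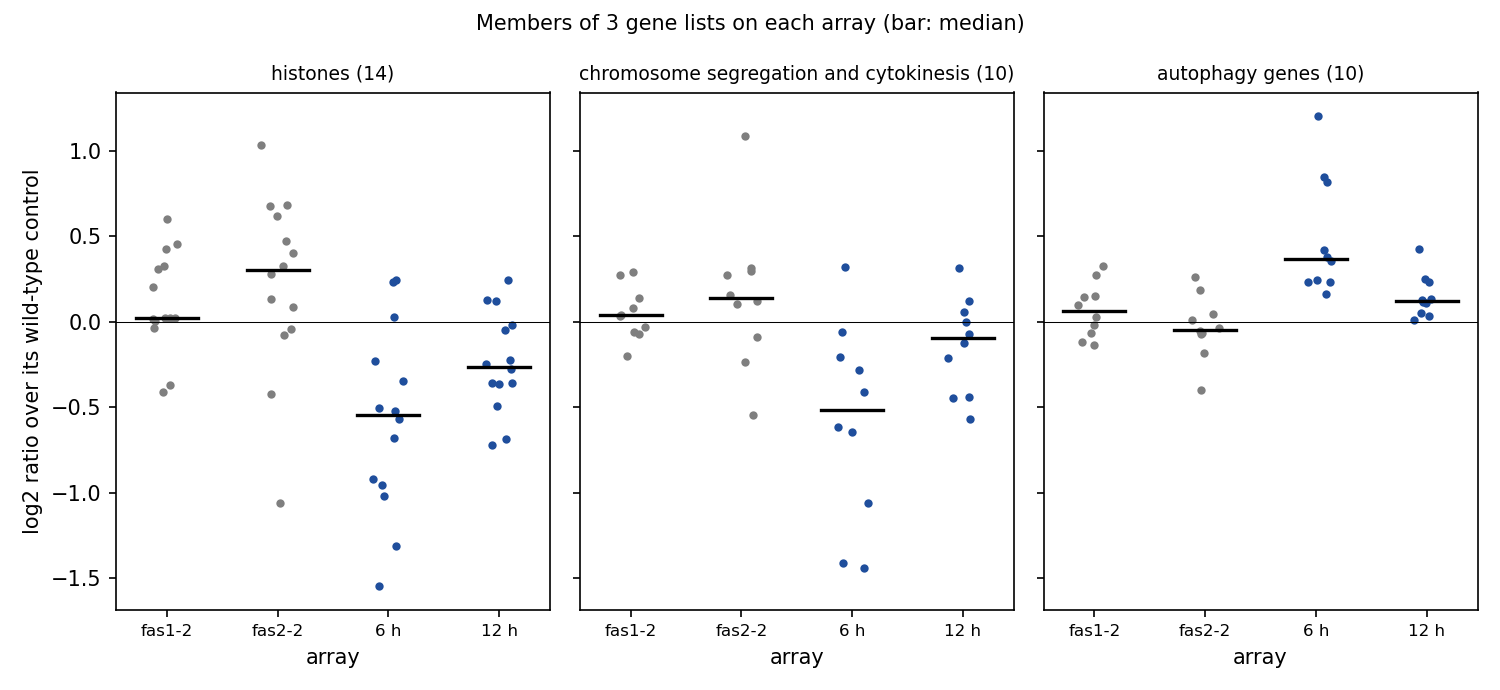
Log2 ratio over its wild-type control of each member of the histone list (14 genes), the chromosome segregation and cytokinesis list (10 genes) and the autophagy list (10 genes) on the 4 arrays, with a bar at the median. The histone medians lie at 0.02, 0.31, -0.55 and -0.26 from left to right, and the autophagy medians are highest at 6 h, at 0.37.

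The 2 times were compared by value, without a test. Their ratios correlated across genes at a Pearson r of 0.30 (Spearman 0.377). At both times 26 genes were at least 2-fold higher and 6 at least 2-fold lower, where independent lists would share 1.6 and 0.69. Simulated unchanged genes gave 18.7 at 2-fold the same way at both times without a shared control. With a control shared by the 2 times and as variable as the other RNA they gave 112.5. Whether the 2 times shared a control is not stated either. Opposite 2-fold values were seen for 20 genes, where independent lists would give 2.14, a number that ignores that some genes vary more than others. Simulated unchanged times without a shared control were nearly uncorrelated (r of 0.009). About as many opposite genes as the 18.7 same-way ones would then be expected. The simulated variances were taken from the measured differences between arrays, to which the 20 genes themselves contribute. The simulation therefore cannot decide whether the 20 are an excess. Of the 20, 16 were high at 6 h and low at 12 h. Among these were AT3G28510 (3.08 at 6 h, -1.66 at 12 h), the carnitine transporter gene OCT1 (AT1G73220; 3.28, -1.26), the chitinase gene CHI (AT2G43570; 1.68, -1.88) and the glutathione transferase gene GSTF3 (AT2G02930; 1.36, -1.23). AT2G32140 (3.29, 0.92), AT3G60420 (2.98, -0.14) and STZ (1.16, 0.02) were also higher at 6 h. The cold and drought genes COR15A (AT2G42540; -1.56, -0.17) and KIN2 (AT5G15970; -1.37, -0.16), AT2G13150 (-3.92, 0.00), AGL41 (AT2G26880; -2.94, 0.12) and AT3G02120 (-2.47, -0.72) were low at 6 h. Genes high at 12 h were SHT (AT2G19070; -1.11, 3.39), an acyltransferase of the tapetum, ATA27 (AT1G75940; -0.37, 2.83), known from anthers, and AT5G58400 (0.60, 2.37). AT1G67270 (-0.42, -4.22), the nitrate transporter gene NRT2.5 (AT1G12940; 0.77, -2.90) and AT4G25790 (0.71, -2.53) were low at 12 h. The tubulin genes were below 0 in 9 of 10 cases at 6 h and above 0 in 10 of 10 at 12 h, with medians of -0.27 and 0.10. The 18 cytochrome P450 genes had medians of 0.07 and -0.28.

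The third comparison asked whether the mutants and irradiated wild type shared a response. A gene-specific dye effect cancels in the difference between the settings. No gene passed in limma for that difference; the smallest adjusted p was 0.129, and 1326 genes had an unadjusted p under 0.05. Among the largest differences were those of AT3G15450 (-2.69 in the mutants, 0.47 after irradiation), AT2G20670 (-2.35, 0.53), AT5G42850 (-3.62, 0.30), AT5G62080 (-0.97, 1.99), AT1G23390 (-2.23, 0.46), AT3G15630 (-1.77, 0.75), AT1G27030 (2.14, -0.32) and AT4G31570 (2.05, -0.25). ZCF37 (AT1G59590) had means of -1.42 and 1.28, and the expansin-like gene EXLB1 (AT4G17030) of 1.16 and -1.27. AT3G45730 was above wild type in every condition, with means of 1.69 in the mutants and 4.34 after irradiation, and AT5G62280 below it, with means of -1.47 and -1.37. These 2 were the only named genes at least 2-fold the same way on all 4 arrays.

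By limma, 0 genes changed in both settings, since limma called 0 after irradiation. At 2-fold on both arrays of a setting there were 85 genes in the mutants and 32 after irradiation, and 2 were shared, AT3G45730 and AT5G62280, where independent lists would share 0.29. Random lists understate chance here, because variable genes pass on every array: simulated unchanged genes without any shared control gave 14.6 and 18.7 genes at 2-fold and 1.72 shared. That simulated count includes genes moving in opposite directions between settings, while the 2 shared genes each moved the same way. With a control shared within each pair it was 17.1. The simulated counts are over all genes and therefore do not decide whether these 2 are shared by chance. The means of AT3G45730 (SE 0.24) and AT5G62280 (SE 0.11) were large beside their own SE in each setting. Neither gene passed in limma in either setting, and the SE leaves out dye effects and the control's own spread. The means of the settings correlated across genes at 0.148, with a covariance of 0.014. For simulated unchanged genes that correlation was 0.002 without a shared control and -0.001 with one within each pair. A single control for all 4 arrays gave 0.667, with a covariance of 0.0781 and 36.5 shared genes. The simulated values with a shared control rest on the assumption that the control varies as much as the other RNA.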

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

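All tests in this part were chosen after the results they bear on had been seen. Between the 2 mutants, 2 genes were at least 2-fold in opposite directions, AT3G57470 (1.37 in fas1-2, -1.56 in fas2-2) and PDC3 (AT5G01330; -1.17 and 1.43); this difference was not tested. Between 6 h and 12 h, 20 genes were at least 2-fold in opposite directions, also untested, and 4 of them were low at 6 h and high at 12 h: SHT, AT2G03740, AT2G28960 and GILT.

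Features outside the gene tests carried large signals. Among the 13240 features without a single gene name, 115 were at least 2-fold the same way in both mutants (60 higher, 55 lower) and 90 were so at both times after irradiation (73 higher, 17 lower). A further 482 were at least 2-fold the same way on all 4 arrays, of which 475 were lower in red. The unnamed feature highest by the smaller of its 2 values after irradiation had log2 ratios of 4.55 at 6 h and 4.09 at 12 h, with 2.02 in fas1-2 and 1.46 in fas2-2, and 6 of the others exceeded 3 at both times. Of these, the feature at 4.35 and 3.62 was at 1.11 in fas1-2 and 2.03 in fas2-2, and that at 3.85 and 3.75 at -0.15 and 0.94. The unnamed feature highest in both mutants (3.29 and 3.72) was at -0.11 at 6 h and -0.04 at 12 h, while one at 2.75 and 2.59 was at 2.06 and 1.21. Genes of unnamed features are not analysed here, so the count of genes shared by the settings covers named genes only.

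The agreement of the 2 mutants (r of 0.523 across genes) was set against 2 technical explanations. A gene-specific dye bias common to all arrays would make mutant and irradiated arrays correlate about as well as the mutants do with each other. Over the 9253 named genes the highest such correlation was 0.147, which argues against dye bias as the main source there. Over all features those correlations were 0.599 to 0.662, beside 0.764 between the mutants. All features include 475 unnamed spots at least 2-fold lower in red on every array, and how far these raise the values was not tested. By rank (Spearman), features without a single gene name gave 0.263 to 0.321 between settings, beside 0.564 between the mutants. The values over all features therefore do not tell whether a dye bias reaches beyond those spots. A wild-type RNA shared by both mutant arrays gave 0.495 in simulation, but that value follows from the assumption that control and mutant RNA vary equally, so the simulation decides nothing. A shared control cannot be told apart from a common effect of losing CAF-1, because the labels do not say which RNA was used and each array has its own single control channel.

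The low histone and chromosome segregation genes after irradiation (24 genes, median -0.55 at 6 h and -0.22 at 12 h) were tested against 3 explanations. Dye bias would cancel between the settings, but the median of mutants minus irradiated over these genes was 0.571, outside the range of -0.124 to 0.093 that held the central 95% of random lists. A shift of the whole 6 h array could not be tested by centring, because the array came centred and the median stayed at -0.547. Random lists on that array lay within -0.092 to 0.101, so these genes were low relative to its other genes. A shift that moves all genes alike would not set them apart in this way. Whether the submitters' centring hid a shift cannot be told. Fewer dividing cells in the sampled tissue for reasons other than the dose stay open: only 1 meristem marker, CLV3, had a named probe, with a mean of -0.033, so this cannot be told apart from an effect of the irradiation.

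Of the 85 genes at least 2-fold the same way in both mutants, 30 lay on chromosome 5, where an even spread over measured genes would place 20.3 (permutation p = 0.0107, not corrected for the 5 chromosomes). Whether close neighbours account for it depends on the distance, of which 4 were tried: 18 of the genes had another within 10 measured genes, inside the range of 6 to 24 from 10000 random placements, and 2 and 10 had another within 1 and 5, also inside, but 38 had another within 20, above 16 to 37 (permutation p = 0.0189). Neighbours that move together therefore cannot be told apart. The fullest run of 500 measured genes in the order of TAIR10.1 held 16 of them, the only run length tried, above the range of 8 to 13 (permutation p = 0.0023), from AT5G41860 to AT5G54090, with 11 higher and 5 lower. After irradiation the fullest run held 6, within 4 to 7. A candidate explanation is a long linked segment that differs between the wild-type and mutant lines in sequence rather than through CAF-1. It was found and tested on the same data, and regional control of expression by CAF-1 was not tested. FAS1 (AT1G65470) lies on chromosome 1, and FAS2 (AT5G64630) lies on chromosome 5 outside this run. Linkage to FAS1 therefore cannot place such a segment in fas1-2, and whether both mutant lines carry one is not known. DFR, UF3GT, PDF1.2, AT5G42850, AT5G49500, AT5G52760, AT5G53820, AT5G51440 and AT5G53150 lie in this run.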

How the results depend on the processing

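The fits named as chosen after seeing the data were added late; the rest were planned. The call counts are fragile. The 11 genes changed in the mutants became 0 with centring, with scaling to a common spread, with robust moderation and with only the 2 mutant arrays, and 0 to 0 over fits that each left out an array; they became 177 at an adjusted p of 0.10 and 756 over all features, which include 475 unnamed spots at least 2-fold lower in red on every array. Irradiation gave 624 over all features and 0 otherwise, and the difference between settings gave 0 in every fit. Genes with an exact zero left out (chosen after seeing the data) or single probes again gave 11, all 11 shared with probes averaged. With an array left out, its partner is assumed to vary like the other setting. Genes changed in both settings became 2 when taken as 2-fold on both arrays of each. The cause was not tested, except that fits on fewer arrays have fewer degrees of freedom.

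Lists called after irradiation went from 3 to 0 with an estimated correlation and to 0 with only the earlier lists (chosen after seeing the data), and ranged from 1 to 9 over fits that each left out an array; the 1 without 6 h was the P450 genes, and the 9 came without 12 h. With the 3 genes put back, the histones had an adjusted p of 0.0344. No list was called in the mutants in any setting. Probes at least 1.5-fold numbered 772 in fas1-2, 887 in fas2-2, 784 at 6 h and 531 at 12 h; at least 3-fold, 76, 85, 59 and 44; and over all features, 1118, 1237, 1215 and 1030. Scaling moved the 12 h count from 155 to 250.

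Correlations over all features were 0.764 between mutants, 0.734 between times, 0.599 and 0.662 for fas1-2 with 6 h and 12 h, and 0.619 and 0.648 for fas2-2. Spearman values were 0.377 between times, 0.104 and 0.20 for fas1-2, and 0.163 and 0.178 for fas2-2. Over genes at least 2-fold on an array the Pearson values were 0.264 between times, -0.004 (turned in sign) and 0.105 for fas1-2, and 0.076 and 0.09 for fas2-2. If the deposited values were log2 or natural logs, 1 or 5 of the 40 genes ranked by size would be at least 2-fold on both arrays, in place of 36. In 563 refits of single named genes, 88 lost a call, all of them among the 11. A turn in sign was counted only for genes called in a fit, and none was counted. Genes ranked by size within a setting were picked for the same sign on both arrays. Leaving out an array could not turn those, so the absence of turns says little. No paired analysis was possible because each condition had 1 array. Signal over background could not be judged.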

Other observations

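Every grouping in this part was chosen after the values had been seen. The named genes that stood highest at 12 h included 3 known from anthers, AMS, SHT and ATA27, in plants labelled as rosette leaves or seedlings without roots. At 6 h AMS was at 1.73, SHT at -1.11 and ATA27 at -0.37, and in the mutants AMS was at -1.54 and 0.00, SHT at 0.00 in both and ATA27 at -0.62 and -1.27. The AMS value in fas2-2 and the SHT value in fas1-2 were 0. Signal over background could not be judged, so it is not known whether AMS and SHT were above background. No flower marker of the lists fixed before the data were examined had a named probe, so flower tissue was not assessed.

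Of the 10 genes lowest in both mutants, 6 were above 0 at both times after irradiation. AT5G42850 was at 0.39 at 6 h and 0.21 at 12 h, AT3G15450 at 0.33 and 0.60, AT2G20670 at 0.46 and 0.61, AT1G23390 at 0.48 and 0.43, AT5G19120 at 0.47 and 0.57 and AT3G15630 at 0.53 and 0.96. The other 4 were AOP3 (-1.49 and -0.15), PDF1.2 (-0.17 and -1.71), AT4G19630 (-0.29 and 0.07) and AT1G35320 (0.36 and -0.74). Some other genes low in the mutants were high at 6 h, but AT5G52760 and GSTF3 were low at 12 h, as in the mutants. STZ was low in the mutants and at 1.16 at 6 h. AT5G52760 was at -1.60 and -1.56 in the mutants, 2.01 at 6 h and -1.15 at 12 h. It lies in the same stretch of chromosome 5 as DFR. GSTF3 was at -1.39 and -0.72 in the mutants, 1.36 at 6 h and -1.23 at 12 h. The clock gene GI (AT1G22770) was at -0.15 and -0.51 in the mutants and -0.46 and -0.25 after irradiation, and the trichome gene TRY (AT5G53200) at -0.22, -0.18, -0.42 and -0.14. No explanation was tested.

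The light-harvesting gene LHCB4.2 (AT3G08940) was at -1.96 in fas2-2 and -0.03 in fas1-2, while its close relative LHCB4.1 (AT5G01530) was at -0.14 and 0.10. The thionin gene THI2.1 (AT1G72260) was at 1.3 in fas1-2 and -0.01 in fas2-2, and GSTU25 (AT1G17180) at 1.28 and -0.08. The reference genes EF1A (AT5G60390), TIP41 (AT4G34270) and SAND (AT2G28390) lay between -0.33 and 0.27 on all 4 arrays.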
